A study of Nannochloropsis oceanica with 44 samples.

How the data were processed

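The series profiled transcripts of Nannochloropsis oceanica CCMP1779 by RNA sequencing of total RNA. The labels list 44 libraries in 11 groups of 4: the start of nitrogen deprivation (0 h), 5 times of deprivation (6, 12, 24, 48 and 72 h, written N-) and 5 times after resupply of nitrogen to cells that had been deprived for 72 h (the same hours, written NR). Within a group the libraries carry the letter A or B and a number 1 or 2. Per the labels' protocols, 2 biological replicates were harvested at each time point, and the labels do not say whether the letter or the number marks them.

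Per the labels' protocols, single-end reads of 50 bases were made on an Illumina HiSeq and trimmed with Trimmomatic 0.32. They were aligned with STAR 2.3.0e to the CCMP1779 assembly, with unique mapping only, at most 4 mismatches and introns of at most 10000 bp. Reads on exons were counted per gene with HTSeq 0.6.1, per the labels' protocols. The authors then used DESeq2 to test the condition (deprivation or recovery) and its interaction with time, with a log2 fold change over 1 and a Benjamini-Hochberg adjusted p-value under 0.01. The genes that passed were split into 4 clusters by k-means with a Pearson correlation distance in MeV 4.8.1, per the labels' protocols. Unique mapping removes reads shared by near-identical genes, so paralogs and repeated gene families would be undercounted.

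The 4 deposited tables hold these called genes, 1 table per cluster, with 1 value on a log2 scale for each gene at each of 10 time points, as the authors made it. The scale was inferred from the deposited values, which run from 1.46 to 19.5 and have the size of read counts when 2 is raised to them, and no file header names it. How the authors scaled the libraries, which log2 transformation they used and how they joined the 4 libraries of a time point are not given in the sources used here. A transformation that shrinks low counts would make the differences of weakly expressed genes too small. The other deposited number is the authors' row number in the clustering input, which runs from 1 to 2489 with each number used once over the 4 tables. Read depth per library is unknown here, and no value carries an error or a number of replicates. The 0 h group has no column in these tables and was not analysed here.

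The design fixed before the data were examined foresaw tests across libraries and 3 comparisons against 0 h. With 1 value per time point no test of a difference between time points was possible, so differences are described by size. A gene is called higher or lower between 2 time points where its log2 values differ by more than 1, which is 2-fold. The earliest deposited time, 6 h N-, took the place of 0 h, a choice made after seeing the tables. Columns of per-sample values left without a match numbered 0, so none is mentioned further. Levels and differences are the authors' values and simple differences between them, computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. All counts are over the called genes only, since genes that did not pass the authors' test are not part of the tables used here. Called genes are not neutral for scaling, so neither the deposited nor a centred scale is known to be right. As a check, each comparison was repeated with every column centred on its median over the called genes. The report gives the centred values for its main comparisons. That median follows the largest clusters. Between 12 h and 24 h NR it rose by 1.76, while the median difference of cluster 3 was 3.78. A cluster that turns with centring may therefore turn only because other clusters moved. The tables of different clusters were taken to share 1 scale because they come from 1 clustering input.

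The identifiers are those of a gene annotation pipeline. They name the gene finder (augustus or snap), whether the model was promoted by evidence (prefix maker) or is a prediction on masked sequence, the contig (nanno_ and a number) and a gene number on it. None of the 2489 identifiers occurred in the reference table used for gene names, which holds 160 genes of the plastid (125) and mitochondrion (35) of the related strain IMET1. Gene functions, coordinates and exon structure were therefore not used here, and the 25 functional gene lists fixed beforehand, among them nitrogen assimilation, photosystems, lipid synthesis, the cell cycle and markers outside the alga, could not be applied and give no result. Under the rule for tables without names, at most 2 identifiers that were higher and 2 that were lower are named per comparison and per cluster, by the largest difference.

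Clusters were recomputed by k-means with correlation distance (100 seeded starts; k = 4, 3 and 5). Same-contig pairs of called genes were compared with 10000 permutations of the contig labels. Profiles of the 2489 genes were simulated from the mean profile of each gene's deposited cluster, with noise of a chosen SD of 0.5. On these the k-means, with fewer starts, put 98.1% of genes back in their cluster. That checks the procedure and does not show that the deposited clusters are distinct. In 100 data sets with shuffled clusters the contig permutation test gave p at or under 0.05 in 7.00%, and with 20 percent of later genes given the cluster of the first gene on their contig it gave p = 0.001, the smallest that its run could give.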

Results

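Nannochloropsis oceanica is a marine unicellular alga studied for the oil it stores when nitrogen runs out. The study followed its transcripts as cells entered nitrogen deprivation and as they left it again. The strain CCMP1779 was grown in continuous light, moved to nitrogen-free medium for up to 72 h, and then returned to medium with nitrogen for up to 72 h. The labels list 44 RNA-seq libraries in 11 groups of 4. The tables analysed here hold 2489 genes that passed the authors' test, with 1 log2-scale value per gene for each of 5 times of deprivation (N-), from 6 h to 72 h, and for the same 5 hours after resupply (NR). The scale was inferred from the values, and genes have identifiers but no names. Replicate values and library depths were not analysed here, so no difference between time points has an error or a p-value, and whether any of them exceeds the spread between cultures cannot be said. Genes are called higher or lower where the values differ by more than 1, which is 2-fold.

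The authors' 4 clusters separated 2 large and 2 small groups of genes. Cluster 3 was the largest with 872 genes (35.0%), followed by cluster 1 with 798 (32.1%), cluster 4 with 418 (16.8%) and cluster 2 with 401 (16.1%). The median gene covered 3.11 on the log2 scale between its lowest and highest time point. Cluster 3 had the widest median range, 3.91, and cluster 1 the narrowest, 2.63. In cluster 1 the highest value fell at 6 h NR for 548 genes and at 12 h NR for 172. Cluster 2 was the mirror of this, with its lowest value at 6 h NR for 223 genes and at 12 h NR for 121. Cluster 3 genes had their lowest value at 12 h NR in 757 cases and their highest at 24 h NR in 662. Cluster 4 genes had their lowest value at 6 h NR in 248 cases and their highest at 12 h N- in 178 or at 48 h NR in 168. These profiles are what the clusters were made from, so they describe the groups and are not separate findings. Recomputed k-means with k = 4 put 2463 genes (99.0%) in the deposited cluster.

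**Figure D1:**
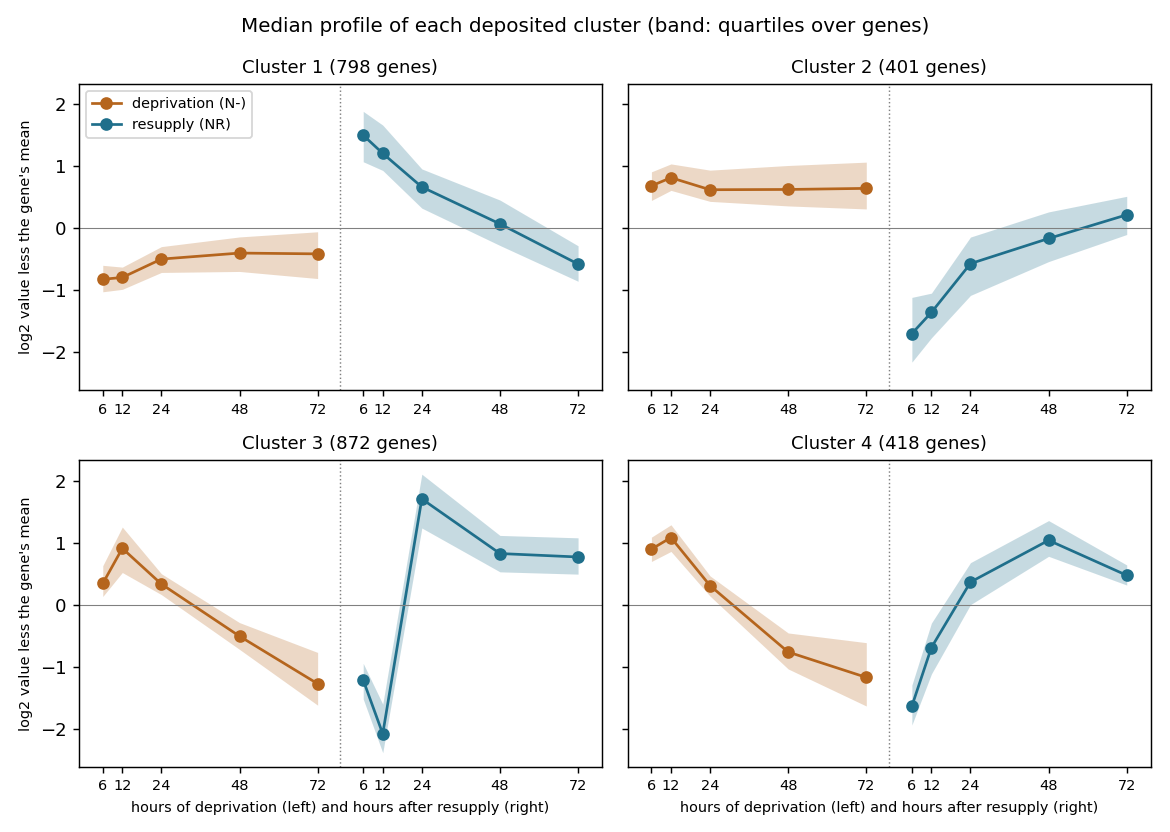
Median profile of each deposited cluster. The vertical axis is the log2-scale value less the gene's own mean over the 10 time points, the horizontal axis gives hours of deprivation (brown) and hours after resupply (blue), points are medians over genes and bands are quartiles over genes, not replicate error. Cluster 3 lies at -2.08 at 12 h NR and at 1.71 at 24 h NR.

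The first comparison asked which genes shifted as deprivation went on. Because the 0 h group is not in the tables used here, 72 h N- was set against 6 h N-. Genes of clusters 3 and 4 were lower at 72 h, and few genes of the other clusters passed the 2-fold limit in the values as deposited. In cluster 4, 368 of 418 genes were lower and 0 were higher, with a median difference of -2.06 (quartiles over genes -2.63 and -1.37). In cluster 3, 667 of 872 genes were lower and 0 were higher, with a median of -1.57. In cluster 1, 91 genes were higher and 32 lower, with a median of 0.42, and in cluster 2, 28 were higher and 8 lower. Over all clusters 119 genes were higher and 1075 lower.

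Counted from 6 h N-, most of the lowering in the medians of clusters 3 and 4 came after 24 h N-. Lowering before 6 h N- cannot be seen here. At 12 h N- only 83 of the 2489 genes (3.33%) differed from 6 h N- by more than 2-fold, and at 24 h N- 177 genes did (7.11%). Cluster 3 was 0.57 above its 6 h value in the median at 12 h N- and 0.82 below it at 48 h N-, or 0.37 above and 0.31 below after centring on the median of the called genes. Cluster 4 was already 0.59 below at 24 h N- and 1.67 below at 48 h N-, when 357 of its genes were lower. The gene with the largest drop was augustus_masked-nanno_1644-abinit-gene-0.9 of cluster 4, on contig 1644, which went from 16.57 at 6 h N- to 9.47 at 72 h N-, a difference of 137-fold. A second cluster 4 gene, snap_masked-nanno_712-abinit-gene-0.3, went from 11.46 to 6.69. Both fell earlier than the median of their cluster, the first to 11.03 at 24 h N- and the second to 8.14 at 12 h N-. In the other direction, snap_masked-nanno_537-abinit-gene-0.1 of cluster 1 went from 3.50 to 8.35, and augustus_masked-nanno_748-abinit-gene-0.0 of cluster 2 from 4.59 to 8.87. The median of all called genes was 0.84 lower at 72 h N- than at 6 h N-. Relative to that shift, clusters 3 and 4 were still mostly lower (315 and 244 genes lower, 7 and 0 higher). Cluster 1 then had 574 genes higher and 14 lower and cluster 2 had 157 higher and 1 lower, and the split over all clusters turned to 738 higher and 574 lower.

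The second comparison asked how cells responded in the first hours of resupply, with 6 h NR set against 72 h N-. Clusters 1 and 2 moved apart. In cluster 1, 673 of 798 genes were higher and 2 lower, with a median difference of 1.90 (quartiles over genes 1.32 and 2.50). In cluster 2, 367 of 401 genes were lower and 0 higher, with a median of -2.34 (quartiles -3.01 and -1.65). Clusters 3 and 4, which were lower at 72 h than at 6 h N-, moved less. Their medians differed from 72 h N- by 0.07 and -0.32, with 31 genes higher and 87 lower in cluster 3 and 13 higher and 108 lower in cluster 4. In all, 717 genes were higher and 564 lower. Relative to a shift of -0.33 in the median of all called genes, 834 were higher and 452 lower, clusters 1 and 2 went the same way as before, and cluster 3 turned to 76 higher and 43 lower. The median of cluster 4 then became 0.01, with 25 genes higher and 64 lower.

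The levels reached in these hours lay outside the whole range seen during deprivation for many genes. At 6 h NR, 631 genes of cluster 1 were more than 2-fold above their highest deprivation value, and 335 genes of cluster 2 were more than 2-fold below their lowest one. After centring these were 727 and 202 genes. The gene augustus_masked-nanno_497-abinit-gene-0.17 of cluster 1 went from 9.17 at 72 h N- to 15.10 at 6 h NR, 60.9-fold higher, and was still at 13.20 at 24 h NR. The cluster 1 gene augustus_masked-nanno_2434-abinit-gene-0.0 went from 7.30 to 12.92. In cluster 2, snap_masked-nanno_186-abinit-gene-0.7 went from 11.02 to 4.77, 76.1-fold lower, and augustus_masked-nanno_494-abinit-gene-0.1 from 11.50 to 5.29. Exceptions within cluster 3 were snap_masked-nanno_4636-abinit-gene-0.2, which was higher at 6 h NR (8.83 against 5.62), and snap_masked-nanno_5892-abinit-gene-0.2, which was lower (6.05 against 8.98).

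Between 6 h and 12 h NR clusters 3 and 4 parted. In cluster 3, 311 genes were lower at 12 h than at 6 h and 2 were higher, with a median difference of -0.82. In cluster 4, 178 genes were higher and 1 lower, with a median of 0.87. Clusters 1 and 2 were mostly within 2-fold, with 55 and 65 genes past it.

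The largest number of differences between successive time points was found between 12 h and 24 h NR, where 1495 of 2489 genes (60.1%) differed by more than 2-fold. This interval spans 12 h and the one before it 6 h. Each of the 872 genes of cluster 3 was higher at 24 h NR, with a median difference of 3.78 (quartiles over genes 2.95 and 4.39), which is 13.7-fold. In cluster 1, 232 genes were lower and 2 higher, with a median of -0.61. Cluster 2 had 159 genes higher and 22 lower, and cluster 4 had 207 higher and 1 lower. The median of all called genes was 1.76 higher at 24 h than at 12 h NR. Relative to that shift cluster 3 was still higher, with a median of 2.01 (693 genes, with 0 lower), and cluster 1 lower, with a median of -2.37 (793 genes, with 0 higher), whereas clusters 2 and 4 turned, to 8 higher and 204 lower and to 12 higher and 169 lower. The 1240 higher and 255 lower genes over all clusters then became 713 and 1166.

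A pair of evidence-based gene models of cluster 3 showed the largest step. The model maker-nanno_3221-augustus-gene-0.2 went from 7.17 at 12 h NR to 14.00 at 24 h NR, 114-fold higher, and maker-nanno_342-augustus-gene-0.8 went from 9.04 to 15.83, 111-fold higher. Both had been high at 12 h N- (13.20 and 15.41) and low at 72 h N- (8.74 and 11.05). In cluster 1, augustus_masked-nanno_646-abinit-gene-0.0 went from 10.45 to 5.32 and augustus_masked-nanno_3156-abinit-gene-0.0 from 9.00 to 4.51. Within cluster 2, augustus_masked-nanno_158-abinit-gene-0.0 went from 6.25 to 10.46 and maker-nanno_452-augustus-gene-0.15 from 9.51 to 13.51. Within cluster 4, augustus_masked-nanno_445-abinit-gene-0.2 went from 3.76 to 8.19.

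**Figure D2:**
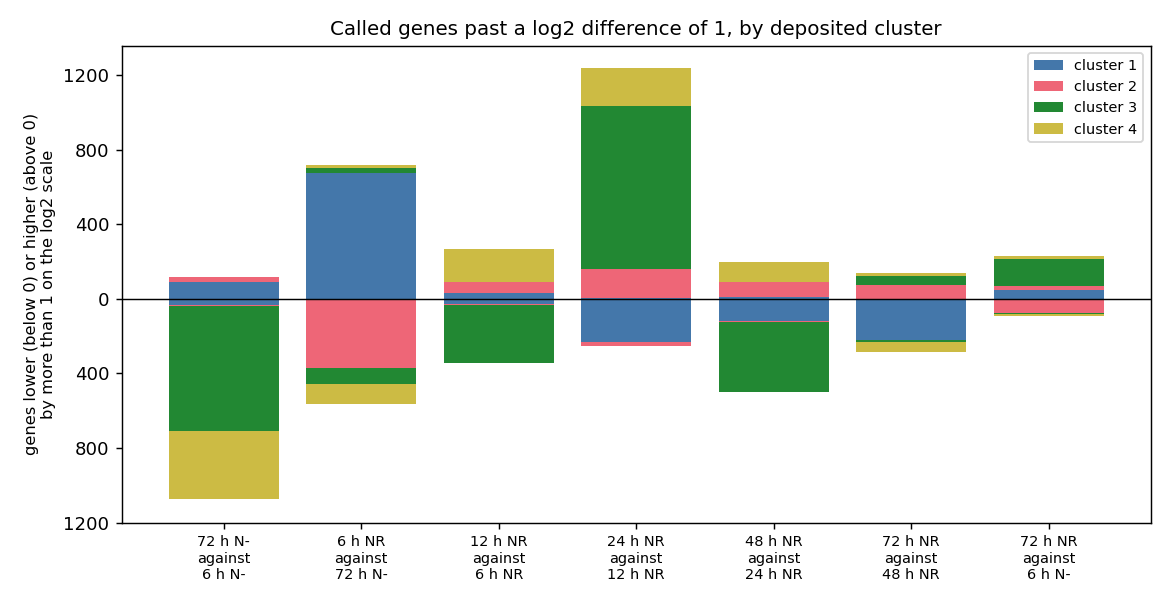
Called genes that differ by more than 1 on the log2 scale between 2 time points. Bars above 0 count genes higher at the first-named time and bars below 0 count genes lower there, coloured by deposited cluster. All 872 cluster 3 genes are higher at 24 h than at 12 h NR. When columns are centred on the median of the called genes, clusters 2 and 4 change direction there, cluster 3 does so between 6 h NR and 72 h N-, and cluster 4, with 14 genes either way at 72 h NR against 6 h N-, has 11 higher and 22 lower.

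After 24 h the steps between successive time points were smaller. Between 24 h and 48 h NR 697 genes passed 2-fold, with cluster 3 lower (371 genes lower, 1 higher) and cluster 4 higher (108 genes higher, 0 lower). After centring 240 genes of cluster 3 were lower and 209 of cluster 4 higher. Between 48 h and 72 h NR 419 genes did, of which 220 were cluster 1 genes that were lower. In the values as deposited, cluster 1 stepped down from a median level of 12.36 at 6 h NR to 11.53 at 24 h and 10.30 at 72 h, beside 10.46 at 72 h N-. Cluster 2 went up from 7.13 at 6 h NR to 9.18 at 72 h NR, beside 9.48 at 72 h N-.

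The third comparison asked where the transcripts stood after 72 h of resupply, against 72 h N-. Clusters 3 and 4 were higher. In cluster 3, 750 of 872 genes were higher and 0 lower (median difference 2.06), and in cluster 4, 321 of 418 were higher and 0 lower (median 1.65). Cluster 1 had 79 genes higher and 90 lower, and cluster 2 had 24 higher and 106 lower. In all 1174 genes were higher and 196 lower. Relative to a shift of 0.92 in the median of all called genes the split was 680 higher and 738 lower, with clusters 3 and 4 still higher (488 and 163 genes, with 6 and 0 lower). Cluster 1 then had 25 genes higher and 460 lower and cluster 2 had 4 higher and 272 lower. The gene augustus_masked-nanno_1644-abinit-gene-0.9, the one with the largest drop in deprivation, stood at 16.17 at 72 h NR, 104-fold above 72 h N-. The gene maker-nanno_58-augustus-gene-0.18 was at 12.41 at 72 h NR and at 6.72 at 72 h N-. The gene snap_masked-nanno_537-abinit-gene-0.1, which had been raised in deprivation, was at 3.02 at 72 h NR, and augustus_masked-nanno_480-abinit-gene-0.0 went from 9.88 to 5.48.

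Genes that had shifted between 6 h and 72 h N- mostly went back towards their 6 h N- level. That level already follows 6 h of deprivation, so a return to the 0 h state could not be judged. Of the 1194 genes that differed more than 2-fold between 72 h and 6 h N-, 1190 (99.7%) had the opposite sign of change from 72 h N- to 72 h NR. The 72 h N- value stands in both differences, and the genes were selected by the authors for a difference between deprivation and resupply. Both favour opposite signs, so the share describes the called genes and does not measure how often a response to deprivation is undone. At 72 h NR 1033 of the 1194 genes (86.5%) were within 2-fold of their 6 h N- level. At earlier times 131 of the 1194 were within 2-fold at 6 h NR, 90 at 12 h, 556 at 24 h and 1023 at 48 h. With columns centred on the median of the called genes these numbers were 590, 496, 627 and 1065, so how late the return came depends on the scaling. Among the 1075 genes lowered in deprivation, 193 were more than 2-fold lower still at 12 h NR, and 57 were after centring. At 24 h NR 470 of these 1075 were more than 2-fold above their 6 h N- level and 127 were at 72 h NR, against 304 and 96 after centring.

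Set against 6 h N-, 72 h NR had 322 genes (12.9%) past 2-fold, 229 higher and 93 lower. Cluster 3 contributed 145 higher and 2 lower genes and cluster 2 had 21 higher and 72 lower, and relative to a shift of 0.08 these were 116 and 2 and 16 and 81. A pair of genes on contig 494, augustus_masked-nanno_494-abinit-gene-0.1 (11.41 at 6 h N- and 7.76 at 72 h NR) and snap_masked-nanno_494-abinit-gene-0.10 (7.94 and 4.54), had the largest differences downward. Their profiles over the 10 time points had a Pearson correlation of 0.99, and whether they are separate transcripts is not known. The largest differences upward were those of maker-nanno_58-augustus-gene-0.18 (7.28 and 12.41) and snap_masked-nanno_742-abinit-gene-0.19 (6.58 and 11.27).

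The authors' own test compared resupply with deprivation, so matched hours were also set side by side. At 6 h 747 genes were higher in NR and 1468 lower, and at 12 h 779 were higher and 1562 lower. At 24 h and 48 h the balance was the other way, with 1094 higher and 262 lower at 24 h and 1193 higher and 209 lower at 48 h. Cluster 1 was higher in NR at 6 h, with a median of 2.33, and at 12 h, with 1.99, and cluster 2 was lower, with -2.39 and -2.15. Cluster 4 had the lowest median at 6 h, -2.58, with 403 of 418 genes lower and 0 higher. At 12 h 356 of its genes were lower and 10 higher, and at 48 h 357 were higher and 0 lower. Cluster 3 was lower in NR at 6 h, with a median of -1.53 (707 genes lower, 1 higher), and at 12 h, with -2.87. It was higher at 24 h, with 598 genes higher and 0 lower. Relative to the medians of the called genes, which differed by -1.17 at 6 h and -1.45 at 12 h, the splits were 828 and 730 at 6 h, 846 and 808 at 12 h, 554 and 452 at 24 h and 542 and 456 at 48 h, so the balance over all genes at 6 h and 12 h turned with the scaling, as it did at 72 h. The directions of single clusters named here did not turn. The medians of cluster 1 became 3.50 and 3.43, and those of cluster 2 became -1.23 and -0.71. Those of cluster 3 became -0.37 at 6 h and -1.42 at 12 h, and 318 of its genes were higher at 24 h. The median of cluster 4 at 6 h became -1.41, with 299 genes lower and 0 higher. At 12 h 86 genes of cluster 4 were lower and 14 higher, and at 48 h 226 were higher and 1 lower.

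Distances between time points were taken over all called genes. The median absolute difference was 0.31 between 6 h and 12 h N-, 0.27 between 48 h and 72 h N- and 0.58 between 6 h and 12 h NR. It was 1.35 between 12 h and 24 h NR, and 0.67 between 24 h and 48 h NR. The largest was 2.34, between 12 h N- and 6 h NR, but with centred columns that pair was at 1.62 and the largest was 1.90, between 12 h and 24 h NR. The time points nearest to 72 h NR were 24 h N- (0.41) and 6 h N- (0.42), and 72 h N- lay at 1.13. Their order depends on the measure. By Pearson correlation across genes 6 h N- was nearest to 72 h NR (0.957), followed by 48 h NR (0.954), and 24 h N- was at 0.935.

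**Figure D3:**
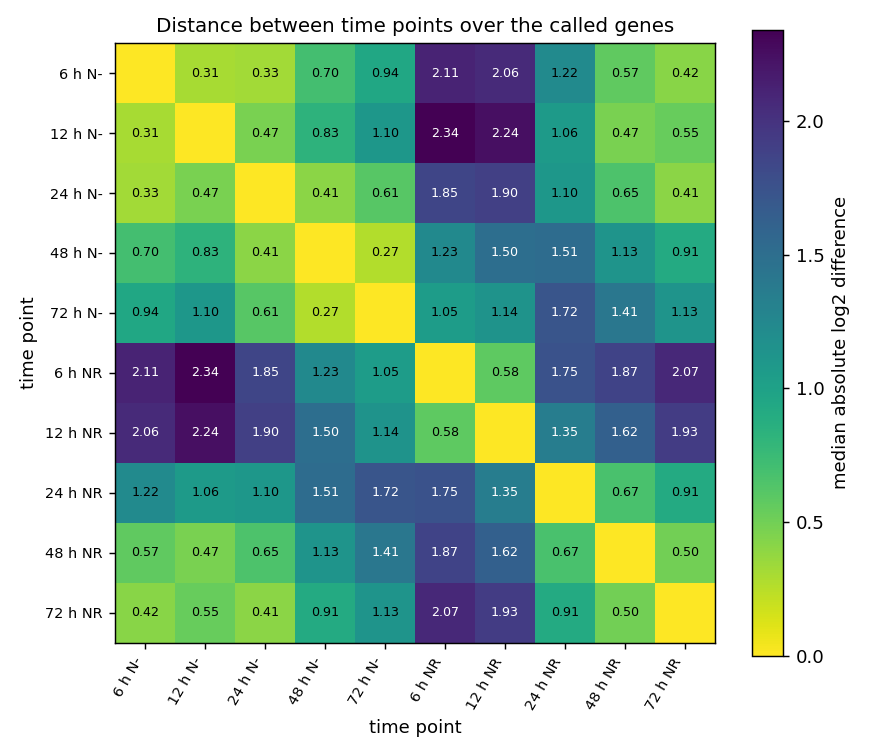
Median absolute log2 difference over the 2489 called genes for each pair of time points, printed in each cell and coloured on the scale at the right. Both axes list the 10 time points. The early resupply times, 6 h and 12 h NR, are near each other (0.58) and far from 6 h N- (2.11 and 2.06), while 72 h NR is near 6 h N- (0.42).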

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

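The tests in this part were chosen after the profiles had been seen. With 1 value per time point no test against replicates was possible.

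A difference between 2 times in the contrast of resupply with deprivation drew attention. In 583 genes NR was more than 2-fold below N- at 12 h and more than 2-fold above it at 24 h, and 574 of these belong to cluster 3 and 9 to cluster 4. The opposite turn was seen in 12 genes, 7 of cluster 1 and 5 of cluster 2. The genes were called for a difference between resupply and deprivation or its change with time, and cluster 3 was formed from these profiles. The turn and its place in cluster 3 follow in part from that selection and are not a separate finding. The difference between the 2 times was not tested. With columns centred on the median of the called genes, the numbers were 209 and 64.

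The pattern behind this is the step between 12 h and 24 h NR, for which 3 technical explanations were weighed. A common scaling difference between the 2 columns would move every gene alike and leave the spread of the step over genes as it was. The quartiles of this step over the 2489 genes were 3.43 apart (bootstrap 95% interval over genes 3.30 to 3.60), against 2.10 (1.93 to 2.26) in the next widest step, from 72 h N- to 6 h NR. The tables therefore argue against a common factor as the whole cause. How much of the step a common factor adds stays open, because none of the called genes is known to be neutral. In clusters 2 and 4 the direction itself turned with centring. An exchange of the 12 h and 24 h NR columns would put 6 h NR nearer to the column named 24 h, but it was farther from it by 1.17 (bootstrap 95% interval over genes 1.10 to 1.24). A deviating library at 12 h or 24 h NR, as the whole cause, would leave the times on either side alike. Cluster 3 was higher at 48 h than at 6 h NR by a median of 2.05 (1.98 to 2.12), or 0.67 (0.60 to 0.73) after centring. Cluster 3 was formed from these same columns, and none of the intervals over genes given here holds error between libraries. The comparison of 48 h with 6 h NR therefore cannot decide about a deviating library. The step was examined because it stood out, so its rank as the widest is not separate support. How much of the step such a library adds stays open, since the values per library were not analysed here. The time since resupply, which the design names, stays open as an untested biological explanation.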

How the results depend on the processing

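With no p-values, only sizes and counts can be compared. The alternatives chosen after seeing the data are those for comparisons with 6 h N-, for 24 h against 12 h NR, for matched hours for contigs and for the hours of return, and the last 3 for opposite signs. Alternatives planned for library values (DESeq2, filters, pseudocounts, leaving out replicates, blocks) and for named gene lists were not run. No paired analysis was possible because each time point has 1 joined value and no column carries a replicate number. Of 47 alternatives, 24 stayed within the limit set for their result (1.5 times for counts) and 23 moved. For the share of opposite signs the limit was a binomial (Wilson) interval over the 1194 genes, 99.1% to 99.9%. It treats genes as independent and is too narrow where genes move together. Settings that shift a result by construction are also counted as moved, so the tally does not measure how stable the results are. Counts past the limit are smaller by construction with a log2 limit of 2. They fell to 507 (72 h against 6 h N-), 636 (6 h NR against 72 h N-), 953 (24 h against 12 h NR), 691 (72 h NR against 72 h N-) and 32 (72 h NR against 6 h N-). At matched hours they fell to 1335 (6 h), 1515 (12 h), 340 (24 h) and 428 (48 h). With a looser limit of 0.5, 72 h NR against 6 h N- gave 1042 genes. The share of deprivation responses with the opposite sign after resupply, 99.7%, was 98.4% with 48 h NR and 100% and 96.4% with log2 limits of 2 and 0.5. With 48 h N- as the deprivation time (838 genes) it was 99.5%. It was 98.9% for these genes when the later change was counted from 72 h N-, so that no value was shared. It was 98.1% with 12 h N- as the reference and 98.8% after centring, and the cause was not tested. Centring left the counts past 2-fold of these comparisons within 1.5 times but changed splits of higher and lower genes. Beside those in the report, 48 h against 24 h NR went from 200 higher and 497 lower to 378 and 278, and 12 h against 6 h NR from 269 and 343 to 305 and 264. At matched hours cluster 1 at 48 h went from 246 and 42 to 75 and 161, and cluster 4 at 24 h from 21 and 8 to 10 and 74. Responders near their 6 h N- level rose with centring from 131 to 590 at 6 h NR and from 90 to 496 at 12 h NR, and lowered genes above it at 24 h NR fell from 470 to 304. Recomputed clusters matched the deposited ones for 99.0% of genes with k = 4, 82.6% with k = 3 and 90.1% with k = 5. Clusters were matched one to one. A deposited cluster therefore goes unmatched with k = 3 and a new one with k = 5, and both shares are lower by construction. With k = 3, 383 of 418 cluster 4 genes joined 863 of cluster 3, and with k = 5, 206 cluster 1 genes formed a cluster with 14 of cluster 2. Same-contig pairs shared a cluster in 42.6% for contigs with 2 to 4 called genes and 43.4% with contigs weighted equally. Depth per library is unknown, so the precision of low values cannot be given.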

Other observations

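The contig tests below were written before their results were seen, and the other values here were chosen after seeing the data. Genes are not independent replicates, so tests across genes have p-values that are too small where genes move together. A small set of genes was high at the last time only. At 72 h NR, 32 genes were more than 2-fold above all 9 other time points: 14 of cluster 3, 10 of cluster 4 and 8 of cluster 2. The model maker-nanno_58-augustus-gene-0.18 exceeded its next highest time by 5.13, having been at 6.67 at 48 h NR. Single-time maxima of that kind numbered 213 at 24 h NR, 212 of them in cluster 3, and 22 at 6 h NR, all in cluster 1. Single-time minima numbered 110 at 6 h NR, 57 in cluster 4 and 51 in cluster 2, and 121 at 12 h NR, 117 in cluster 3. During deprivation at most 1 gene per time was above all others in this way, and 2 after centring. These numbers depend on the scaling. After centring the maxima numbered 14 at 6 h NR, 45 at 24 h NR and 20 at 72 h NR, and those at 12 h NR went from 6 to 31. The minima numbered 9 at 6 h NR and 23 at 12 h NR, and those at 24 h NR went from 8 to 52, 48 of them in cluster 2.

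The summed level was taken as 2 raised to the value and added over the 2489 called genes. The log2 transformation is not known and no correction for gene length is described, so its parts are not shares of transcripts. The 10 highest genes held from 12.9% of it, at 12 h NR, to 17.4%, at 72 h N-, and 15.8% at 6 h NR. The gene maker-nanno_4991-augustus-gene-0.7, chosen after its values were seen, was the highest called gene at 6 of the 10 time points and held 5.83% of the sum at 24 h NR. The row number in the clustering input was lower for genes with a wider range (Spearman rho across genes -0.65), and 49 of the first 100 rows are cluster 3 genes.

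Evidence-based models, with the prefix maker, made up 34.8% of the called genes. They were 46.6% of cluster 1 and 29.2% of the other clusters together (Fisher's exact test, two-sided, adjusted p = 1.5e-16 over 4 clusters), and 27.3% of cluster 3 against 38.8% elsewhere (adjusted p = 1.42e-08). Clusters 2 and 4 had 31.9% and 30.6% (adjusted p = 0.208 and 0.0740). The median level over time points of maker models was 10.31, that of augustus predictions 9.31 and that of snap predictions 7.95. Cluster 1 also had the highest median level of the 4 clusters at each time point. The tests were not adjusted for level, so level and cluster cannot be told apart here.

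Called genes of one contig shared a cluster more often than chance, the hypothesis being that genes on one contig move together. Of 3879 pairs on one contig, 33.6% were in one cluster, against 26.4% to 29.6% in the central 95% of 10000 permutations (p = 0.0001, the smallest they can give), which argues against random placement. Were most contigs with 5 or more called genes from another organism whose transcripts all follow its abundance, most would hold 1 cluster. Only 3 of 99 did (3.03%). An organism that regulates its own genes could fill several clusters, and a few foreign contigs would also give a low share. Contigs with 2 to 4 called genes, where 42.6% of pairs shared a cluster, were not examined for this. Another organism with regulated genes, or a smaller part played by any other organism, therefore stays open. Single transcripts split into several gene models remain a candidate explanation, since 509 pairs correlated above 0.95 (213 to 284 in the central 95% of permutations) and without such pairs the share was 24.1%, inside the permuted 21.9% to 24.9%. Genes of one contig regulated together would give the same result, so split transcripts and shared regulation stay open too.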
